A study of Mus musculus with 12 samples.

How the data were processed

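RNA was taken from the small intestine of 12 BALB/c mice, 6 given TUDCA and 6 given vehicle, and hybridised to Affymetrix mouse gene arrays after biotin labelling with a low-input whole-transcript kit, per the labels' protocols. The description field of the labels names another source, CXCL12-abundant reticular cells, whereas the source, tissue and treatment fields and the series' design text all name small intestine. The latter was followed, and a list of reticular cell markers was tested. The authors deposited 1 log2 value per probe set and array, and the submitters' processing notes name the oligo package and RMA, an algorithm of background correction, quantile normalisation and probe summarisation, without versions. Whether probe sets had been filtered is not given in the sources used here. The deposited log2 values had medians between 5.90 and 5.95 on the arrays, the unit and scale of RMA output. RMA makes the distributions of the arrays alike, so a shift of all transcripts in 1 direction would not be seen, and the median of all log2 differences was 0.01. The table carried no detection calls, so genes near the lower end of the range have compressed differences.

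The 23991 probe sets were named through the platform annotation, under which 21557 named 1 gene, 787 named several and 1647 none. All entered the tests, and only probe sets naming 1 gene were named in the text. Of 21408 genes with a probe set of their own, 148 had more than 1, and for 7 of these some but not all probe sets passed. The choices of test, samples, covariates, lists and the rule for named genes were fixed before the data were examined. Some members of the lists are not analysed here: of 910 genes 797 were measured.

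Differences between TUDCA and vehicle were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on intensity), with the treatment and the number range of the sample as terms. Sample numbers in the labels ran from 57 to 70 in the low range and from 153 to 166 in the high range, and the labels do not say what the ranges stand for. The Benjamini-Hochberg adjustment ran over all probe sets, tests were two-sided and the threshold was an adjusted p of 0.05. The p-values treat the mice as separate samples, 1 per array, going by the sample numbers, since the labels do not otherwise identify the mice. A simulation with the real means and variances, in which 200 of 23991 probe sets were changed between TUDCA and vehicle, recovered 12% of those changed by 0.25 log2 units, 82% at 0.5, 96% at 1 and 100% at 2, and 7.64% of its calls were unchanged probe sets.

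Of 36 gene lists 35 had at least 5 measured members, the exception being the sex-linked genes. Of these, the 4 measured genes of the Y chromosome were low in both groups (log2 means from 2.94 to 3.43) and did not differ (adjusted p of 0.576 or more). For each gene the probe set with the highest mean was taken. Lists were tested against all other genes with camera at a preset correlation of 0.01, and with an estimated correlation as an alternative. A further alternative, fry, tests a list against no change of its own genes, so its counts answer another question than those of camera. A list score, the mean over members of the log2 value minus the gene's mean, was also compared by a two-sided exact permutation test over all 225 relabelings within the number ranges, whose smallest p is 0.00444. A list is described as risen or fallen where both camera and the permutation test passed after Benjamini-Hochberg adjustment over the 35 lists. Camera called 5 lists higher and 12 lower, the permutation test 2 and 6, fry 1 and 4, and camera with an estimated correlation called none. The 8 primary lists were those of MHC class I and class II presentation, the interferon gamma response, the ER stress response, pro-apoptotic and anti-apoptotic genes, inflammatory cytokines and chemokines, and bile acid transport and FXR targets. An FXR target is a gene regulated by the farnesoid X receptor, a nuclear receptor of bile acids.

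Genes were named by rule: the 12 with the largest log2 difference per direction among those past the threshold with the same sign in both number ranges, leaving out clone-style names, up to 4 members with the smallest p of each list, and a fixed set of genes of interest. A further 12 lists were written after the called genes had begun to be read and are reported only among the closing observations. Their p-values were adjusted over these 12 lists alone. The alternatives were a fit without the number range, the replicate number as a block with and without the number range, each number range alone, removal of probe sets dimmer than the median, renewed quantile normalisation, centring of arrays, eBayes without a trend or with robust variances, array weights, 1 probe set per gene, a threshold of 0.1, the mean of all probe sets of a gene, and omission of each array in turn. Scanner files were not used here, so background correction could not be varied, and no genome coordinates are given.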

Results

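Gene expression was measured in whole small intestine of BALB/c mice on day 14 after allogeneic haematopoietic cell transplantation, in which irradiated recipients were given bone marrow and T cells from C57BL/6N donors. This transfer between strains is a mouse model of acute graft-versus-host disease, in which donor T cells attack recipient tissues, the gut among them. Tauroursodeoxycholic acid (TUDCA) is a taurine-conjugated bile acid that is also used as a chemical chaperone. The 6 arrays of the treated group come from mice given 200 mg/kg TUDCA by daily injection into the peritoneum, and the 6 arrays of the vehicle group from mice given the same volume of 200 µl without it. Correlations between the 12 arrays lay from 0.984 to 0.993 across probe sets. Sample numbers in the labels fell into a low range, with 4 vehicle and 2 TUDCA arrays, and a high range, with 2 vehicle and 4 TUDCA arrays. Each difference was estimated within the ranges. The number of arrays limits the precision of every value.

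The comparison of TUDCA with vehicle asks how the bile acid changed the intestinal transcriptome, and the title of the series points to apoptosis and inflammation. In the intestine of treated mice, lists of interferon gamma response, antigen presentation, T and NK cell, enterocyte and bile acid genes fell, while lists of goblet cell and glutathione genes rose, by camera and by exact permutation. The bile acid list had a median member difference of −0.10, smaller than its score difference of −0.26. With an estimated correlation camera called 0 lists higher and 0 lower, with adjusted p from 0.076 to 0.26 with an estimated correlation for these lists. The largest fall was that of S100g, the calcium-binding protein calbindin-D9k of absorptive cells, with a log2 value of 9.16 ± 0.98 (SD, n = 6) under TUDCA and 11.79 ± 0.33 (SD, n = 6) under vehicle. The largest rise was that of Gprc5a, an orphan G protein-coupled receptor, with 9.80 ± 0.44 (SD, n = 6) under TUDCA and 7.78 ± 0.30 (SD, n = 6) under vehicle.

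Of 23991 probe sets, 241 were higher and 364 lower with TUDCA after adjustment in limma, corresponding to 218 and 338 genes, and all 605 had the same sign within both number ranges. Only 17 probe sets rose and 31 fell by more than 1 log2 unit. Without TUDCA replicate 1 the counts were 91 and 151, and without TUDCA replicate 2 they were 107 and 189. Without vehicle replicate 6 they were 147 and 240, and the count of higher probe sets was 157 without vehicle replicate 3 and nearly the same without vehicle replicate 2. The high range alone, with 2 vehicle arrays, gave 6 and 3, and the low range alone gave 169 and 331. With the replicate number as a block together with the number range, the counts over all arrays were 85 and 190.

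Among the genes with the largest falls were S100g (log2 difference −2.77 ± 0.36 SE, adjusted p = 0.0015) and Enpp7, the intestinal alkaline sphingomyelinase, which fell by 2.44 (adjusted p = 0.00948). Plb1, a brush border phospholipase, fell by 2.22 (adjusted p = 0.0115), and Slc5a12, a sodium-coupled monocarboxylate transporter, fell by 2.03 (adjusted p = 0.00171). G6pc, the catalytic subunit of glucose-6-phosphatase, fell by 2.20, Vnn1, a pantetheinase, fell by 1.53. Cyp3a25, a cytochrome P450, fell by 2.36 to a level of 3.54 ± 0.43 (SD, n = 6) near the lower end of the arrays' range. The granzymes of cytotoxic lymphocytes, Gzma and Gzmb, fell by 1.97 ± 0.28 (SE) and 1.55 ± 0.35 (SE). Nos2, the inducible nitric oxide synthase, fell by 1.56, Ubd, a ubiquitin-like protein induced by interferon gamma, fell by 1.49, and U90926 fell by 1.37.

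The genes with the largest rises included Gprc5a (log2 difference 2.15 ± 0.17 SE, adjusted p = 1.76e-05) and Reg4, a lectin of secretory intestinal cells (1.51 ± 0.14 SE, adjusted p = 0.000103). Cldn4, a claudin of tight junctions, rose by 1.25, and Nrg1, a ligand of ErbB receptors, by 1.28. Sprr1a, a cornified envelope protein, rose by 1.23 and Gsta4, a glutathione transferase, by 1.21. Ly6d rose by 1.53, Car1, a carbonic anhydrase, by 1.29, and Ly6g, a surface protein of neutrophils, by 1.26. Mboat1, a lysophospholipid acyltransferase, rose by 1.19, Tnfrsf12a, the receptor of the cytokine TWEAK, by 1.05, and Mptx1, a mucosal pentraxin, by 1.04. Of these 24 genes, 22 moved in the same direction in all 6 TUDCA arrays relative to the vehicle mean of the same number range, and 13 had groups that did not overlap. A total of 15 stayed past the threshold whichever array was left out. The genes were chosen by size and sign on these same arrays, so such agreement is partly given by the choice. The calls of Enpp7, Plb1 and Vnn1 ended without TUDCA replicate 1, that of Car1 without TUDCA replicate 2, and those of Ly6d, Ly6g, Mptx1, Ubd and Gzmb without either. Those of Car1 and Ly6g also ended without vehicle replicate 6, and that of Gzmb without vehicle replicate 1, 3 or 5, with adjusted p up to 0.105 (Car1). Without the number range as a term, the adjusted p was 0.0869 for Gzma and 0.2 for Gzmb.

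**Figure D1:**
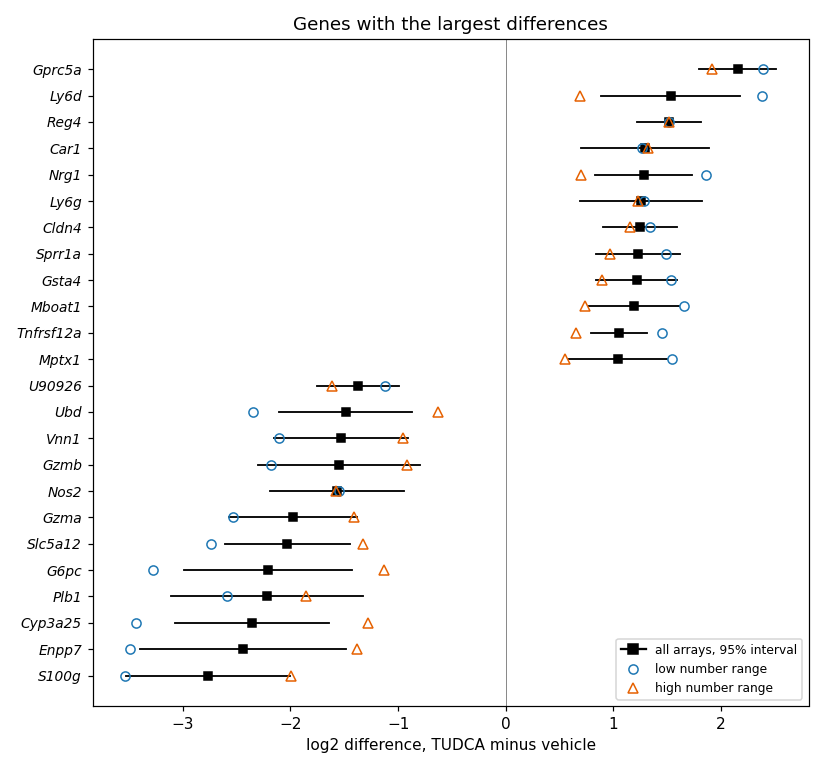
Log2 differences between TUDCA and vehicle (x axis) for the 12 genes per direction with the largest differences (y axis). Squares show the fit over all 12 arrays with 95% intervals, circles the low and triangles the high number range alone. All values of a gene lie on the same side of 0, which the rule for choosing the genes requires. The fits over all arrays run from −2.77 for S100g to 2.15 for Gprc5a.

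Interferon-induced genes and genes of antigen presentation fell together. In the interferon gamma response list, 10 of 25 measured genes fell and none rose (20 fell when adjusted over the list alone). Among them were Gbp8, a guanylate-binding protein, at −1.25 ± 0.17 (SE), the checkpoint ligand Cd274 at −0.91 ± 0.15 (SE), the GTPase Irgm2 at −0.65 ± 0.09 (SE) and the transcription factor Irf1 at −0.50 ± 0.08 (SE). The list score, the mean centred log2 value of the members per array, was lower by a difference of −0.59 ± 0.15 (SE), with adjusted p = 0.0389 by exact permutation and adjusted p = 1.85e-21 by camera. TUDCA replicate 2 had the lowest score (−0.99, the other TUDCA arrays from −0.39 to 0.17), and without it the difference was −0.41. Scores of the groups overlapped. The camera call was lost with an estimated correlation (adjusted p = 0.128 with an estimated correlation). Without the number range term the call of Cd274 ended (adjusted p = 0.054). The chemokines Cxcl9 and Cxcl10 did not pass the test (log2 differences −0.61 and −0.67, adjusted p = 0.208 and 0.161 in limma), nor did Ifng itself (−0.30, adjusted p = 0.16).

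Of 19 measured genes of MHC class I presentation, 7 fell and none rose (15 fell when adjusted over the list alone). They included the peptide-loading genes Tapbp (−0.53 ± 0.06 SE), Tap1 (−0.57 ± 0.11 SE) and Tap2 (−0.54 ± 0.09 SE), the nonclassical gene H2-T23 (−0.70 ± 0.08 SE) and the light chain gene B2m (−0.28 ± 0.05 SE). The list score difference was −0.36 ± 0.06 (SE; adjusted p = 0.0389 by exact permutation, adjusted p = 5.03e-18 by camera, adjusted p = 0.076 with an estimated correlation). Of 17 class II genes, 7 fell and none rose (10 fell when adjusted over the list alone), among them Ciita, the master activator of class II transcription (−0.63 ± 0.11 SE), H2-Ea (−0.69 ± 0.13 SE), H2-Aa (−0.53 ± 0.10 SE) and H2-Eb1 (−0.47 ± 0.10 SE). The class II score difference was −0.27 ± 0.07 (SE; adjusted p = 0.0389 by exact permutation, adjusted p = 1.91e-07 by camera, adjusted p = 0.176 with an estimated correlation). The scores of both antigen presentation lists were lower in all 6 TUDCA arrays than in any vehicle array. Without TUDCA replicate 1 or 2 the single-gene calls of B2m, H2-Aa and H2-Eb1 ended (adjusted p up to 0.0704, 0.0742 and 0.089 in limma), and that of H2-Eb1 also ended without vehicle replicate 6.

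Markers of T and NK cells were lower as well: 8 of 34 measured genes fell and none rose (14 fell when adjusted over the list alone). The T cell receptor complex gene Cd3e fell by 0.93, and the coreceptor genes Cd8a and Cd8b1 fell by 1.03 and by 0.67 respectively. The score difference was −0.41 ± 0.13 (SE; adjusted p = 0.0389 by exact permutation, adjusted p = 4.52e-12 by camera, adjusted p = 0.26 with an estimated correlation), and it was −0.27 without TUDCA replicate 2. The neutrophil and mast cell list was not called (0.09 ± 0.06 SE, adjusted p = 0.301 by exact permutation), and Ly6g was its only member past the threshold. Macrophage and dendritic cell markers (−0.11 ± 0.09 SE, adjusted p = 0.389 by exact permutation) were lower by camera alone (adjusted p = 0.0152, adjusted p = 0.636 with an estimated correlation) with none of 31 genes past the threshold. B and plasma cell markers (−0.08 ± 0.06 SE, adjusted p = 0.385 by exact permutation) were not called, and 1 of 22 fell, Prdm1, a regulator of plasma cells (−0.51 ± 0.13 SE, adjusted p = 0.0499). The call of Prdm1 ended without any 1 of 10 arrays (adjusted p up to 0.186).

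**Figure D2:**
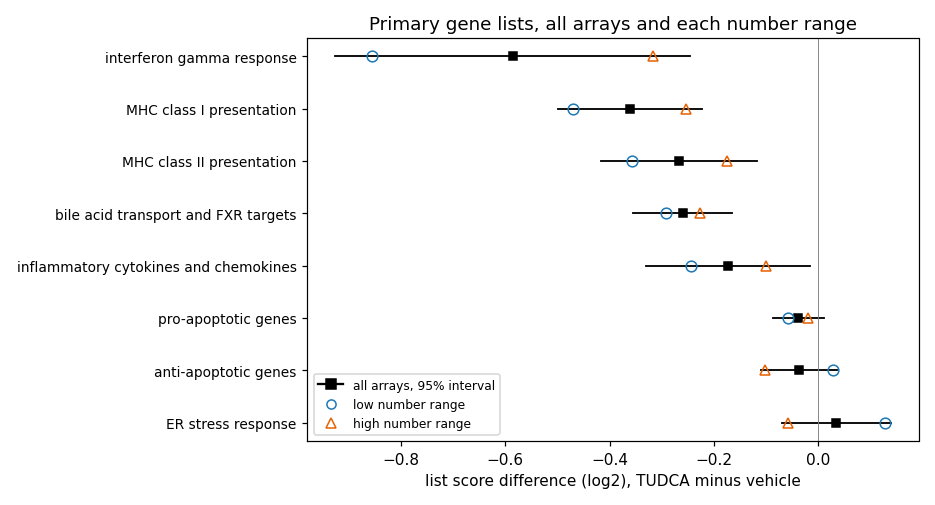
Differences in list score between TUDCA and vehicle in log2 units (x axis) for the 8 primary gene lists (y axis). Squares show all 12 arrays with 95% intervals, circles the low and triangles the high number range alone; the interferon gamma response lies lowest at −0.59 and the ER stress response highest at 0.04.

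Inflammatory cytokines and chemokines were lower by camera alone: of 38 measured genes 3 fell and 1 rose (6 and 1 when adjusted over the list alone). Those that fell were the chemokine Ccl5 (−1.28 ± 0.28 SE, adjusted p = 0.0265), the inflammatory caspase Casp4 (−0.64 ± 0.11 SE, adjusted p = 0.0082) and Nos2, and the member that rose was Il1rn, the interleukin-1 receptor antagonist (0.56 ± 0.11 SE, adjusted p = 0.0148). The calls of Ccl5 and Il1rn ended without TUDCA replicate 1 or 2 (adjusted p up to 0.0669 and 0.0748), and those of Ccl5 and Casp4 without the number range term (adjusted p = 0.102 and 0.086). Ccl5 also missed the threshold without vehicle replicate 3. Tnf, Il1b and Il6 did not pass the test in limma, with log2 differences of −0.43, −0.51 and 0.13 and adjusted p = 0.124, 0.332 and 0.592. Il6 lay between 2.96 and 3.53 on all arrays, near the lower end of their range, so its result says little about Il6. The score difference was −0.17 ± 0.07 (SE; adjusted p = 0.117 by exact permutation, adjusted p = 0.00943 by camera, adjusted p = 0.42 with an estimated correlation). The camera call ended without the number range term (−0.12, adjusted p = 0.259), without TUDCA replicate 2 (−0.11, adjusted p = 0.181) and without vehicle replicate 5 (−0.14, adjusted p = 0.0516). With probe sets dimmer than the median left out, the inflammatory difference was larger, at −0.33, and the camera call stayed (adjusted p = 0.00378). The type I interferon list gave a similar split, with a difference of −0.34 ± 0.18 (SE), adjusted p = 0.3 by exact permutation and adjusted p = 1.26e-08 by camera (adjusted p = 0.478 with an estimated correlation). Of its 28 genes 5 fell, such as Ifit2 at −1.03 ± 0.17 (SE; adjusted p = 0.132 without the number range term), and 12 fell and 1 rose when adjusted over the list alone.

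The lists of apoptosis genes and of the ER stress response were not called by either test over all arrays. Of 31 pro-apoptotic genes 2 fell and 1 rose (4 and 3 when adjusted over the list alone). The death receptor gene Fas was at −0.77 ± 0.10 (SE, adjusted p = 0.00139) and the death ligand gene Tnfsf10, encoding TRAIL, at −0.78 ± 0.15 (SE, adjusted p = 0.0125). Tnfrsf10b, encoding the TRAIL receptor, was at 0.47 ± 0.08 (SE, adjusted p = 0.00566). The calls of Tnfsf10 and Tnfrsf10b ended without the number range term (adjusted p = 0.0508 and 0.0631), and that of Tnfsf10 also without TUDCA replicate 1 or 2. Bbc3, encoding the BH3-only protein PUMA, was at 0.09 ± 0.13 (SE, adjusted p = 0.812). Score differences were −0.04 ± 0.02 (SE, 95% interval −0.09 to 0.01, adjusted p = 0.299 by exact permutation) for the pro-apoptotic and −0.04 ± 0.03 (SE, 95% interval −0.11 to 0.04, adjusted p = 0.408 by exact permutation) for the 13 anti-apoptotic genes. Of the latter none passed over all genes (1 higher and 2 lower when adjusted over the list alone). The pro-apoptotic score lay below the vehicle mean of the same number range in all 6 TUDCA arrays, the anti-apoptotic score in 5. Small shifts of these lists thus stay open. None of the 34 ER stress genes passed, over all genes or when adjusted over the list alone, and the score difference was 0.04 ± 0.05 (SE, 95% interval −0.07 to 0.14, adjusted p = 0.572 by exact permutation). The chaperone gene Hspa5 was at 0.18 ± 0.10 (SE, adjusted p = 0.49) and Ddit3, encoding CHOP, at −0.09 ± 0.10 (SE, adjusted p = 0.772). The ER stress score difference was 0.13 within the low range and −0.06 within the high range, and camera called it in opposite directions there (adjusted p = 0.00121 and 0.0116). Without vehicle replicate 5 camera called it higher (0.09, adjusted p = 0.0185).

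Genes of absorptive enterocytes fell and genes of goblet cells rose. Of 39 enterocyte genes, 14 fell and none rose (19 fell when adjusted over the list alone), with the peptidase genes Ace at −1.20 ± 0.09 (SE, adjusted p = 1.29e-05) and Dpp4 at −0.45 ± 0.06 (SE), the sterol exporter Abcg8 at −0.79 ± 0.07 (SE) and the peptide transporter Slc15a1 at −0.70 ± 0.08 (SE). The score difference was −0.30 ± 0.07 (SE; adjusted p = 0.0389 by exact permutation, adjusted p = 9.2e-18 by camera, adjusted p = 0.076 with an estimated correlation). Of 20 goblet cell genes, 5 rose and none fell (15 and 1 when adjusted over the list alone), including the transcription factor Spdef (0.38 ± 0.08 SE), Bcas1 (0.59 ± 0.13 SE), Capn9 (0.51 ± 0.09 SE) and Guca2a, encoding guanylin (0.30 ± 0.07 SE). The mucin gene Muc2 did not pass (0.27 ± 0.12 SE, adjusted p = 0.3). The goblet score difference was 0.28 ± 0.10 (SE; adjusted p = 0.0389 by exact permutation, adjusted p = 6.43e-09 by camera, adjusted p = 0.225 with an estimated correlation). Vehicle replicates 1 and 6 had the lowest goblet scores (−0.37 and −0.34, the other vehicle arrays from −0.02 to 0.07). In the high range the goblet difference thus leaned on vehicle replicate 6, with vehicle replicate 5 at −0.02 and the TUDCA arrays from −0.03 to 0.15. The calls of Spdef, Bcas1 and Guca2a ended without TUDCA replicate 1 or 2 (adjusted p up to 0.0711, 0.0948 and 0.138), that of Bcas1 also without vehicle replicate 6, and that of Guca2a without any 1 of 8 arrays. Without the number range term those of Guca2a and Capn9 ended (adjusted p = 0.341 and 0.0781).

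Genes of glutathione and oxidative stress metabolism rose: 5 of 22 were higher and none lower (8 and 1 when adjusted over the list alone), with Gsta4, the quinone reductase gene Nqo1 (0.42 ± 0.08 SE), Gclc, encoding the catalytic subunit of glutathione synthesis (0.43 ± 0.09 SE), and the thioredoxin reductase gene Txnrd1 (0.24 ± 0.06 SE). The score difference was 0.17 ± 0.04 (SE; adjusted p = 0.0389 by exact permutation, adjusted p = 0.00114 by camera, adjusted p = 0.128 with an estimated correlation). The calls of Nqo1 and Txnrd1 ended without the number range term (adjusted p = 0.116 and 0.0977), and without TUDCA replicate 1 those of Nqo1 and Gclc ended (adjusted p = 0.0858 and 0.105). The call of Gclc also ended without TUDCA replicate 2, and that of Txnrd1 without any 1 of 10 arrays (adjusted p up to 0.164).

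In the list of bile acid transport and FXR target genes, which also holds enzymes that metabolise bile acids and xenobiotics, 3 of 24 genes fell and 1 rose (5 and 1 when adjusted over the list alone). Those that fell were Cyp3a25, the carboxylesterase gene Ces2a (−1.28 ± 0.18 SE) and the sterol hydroxylase gene Cyp27a1 (−0.74 ± 0.10 SE), and the export pump gene Abcc3 rose (0.59 ± 0.08 SE, adjusted p = 0.0723 without the number range term). The ileal bile acid uptake transporter Slc10a2 (−0.0015 ± 0.08 SE), the bile acid-binding protein Fabp6 (−0.04 ± 0.11 SE) and Fgf15, the enterokine induced by the bile acid receptor FXR (−1.06 ± 0.55 SE, adjusted p = 0.412), did not pass. The list score difference was −0.26 ± 0.04 (SE; adjusted p = 0.0389 by exact permutation, adjusted p = 0.0075 by camera, adjusted p = 0.225 with an estimated correlation). The median member difference was smaller, at −0.10, with 17 of 24 members below 0 and Cyp3a25, Ces2a, Fgf15 and Cyp27a1 the furthest below.

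**Figure D3:**
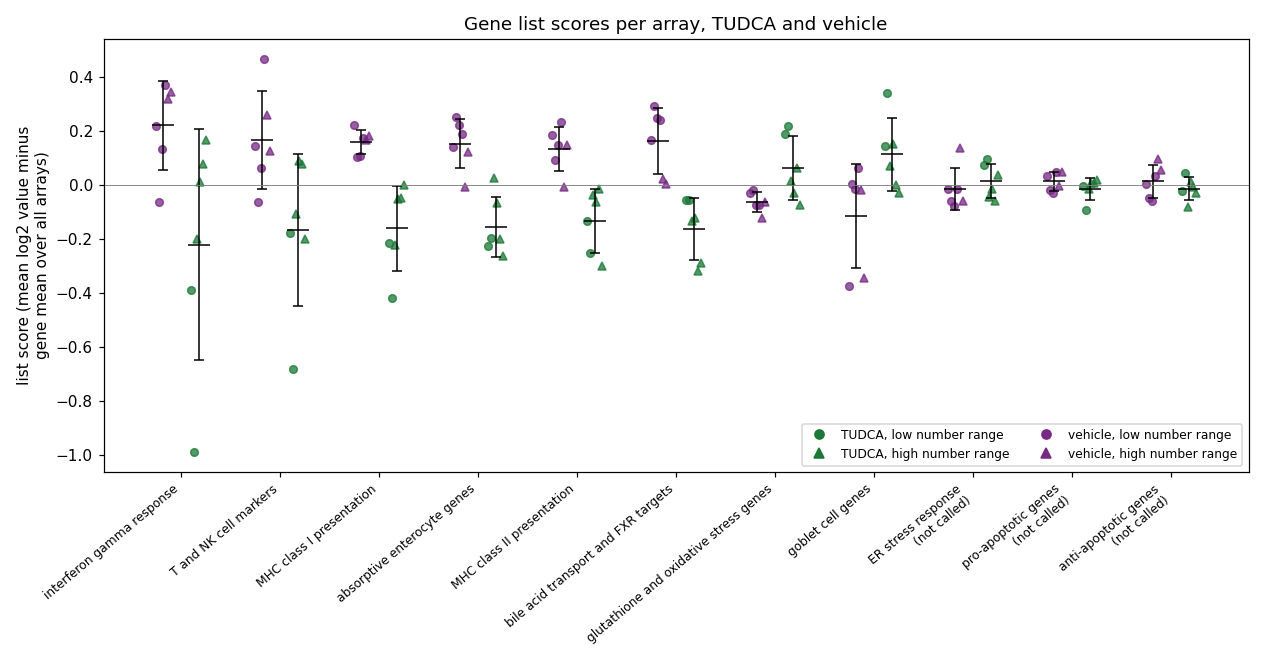
Scores per array in log2 units (y axis) for the 8 lists called by both tests and for 3 lists that were not called (x axis). Points are arrays, coloured by treatment and shaped by number range, and bars show the mean and SD of each group of 6; scores of MHC class I and class II presentation do not overlap between groups, those of the ER stress response do.

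The remaining lists were not called by both tests. By camera alone the ileal segment genes were lower (−0.23 ± 0.08 SE, adjusted p = 0.0519 by exact permutation, adjusted p = 0.0251 by camera, adjusted p = 0.225 with an estimated correlation), with 2 of 15 genes lower, Mep1a (−0.84 ± 0.11 SE) and Clec2h (−0.30 ± 0.06 SE; adjusted p up to 0.0843 without TUDCA replicate 1 or 2). The jejunal genes were not called (−0.08 ± 0.06 SE, adjusted p = 0.385 by exact permutation). Cholesterol synthesis genes were higher by camera alone (0.15 ± 0.05 SE, adjusted p = 0.099 by exact permutation, adjusted p = 5.05e-05 by camera, adjusted p = 0.26 with an estimated correlation), with Msmo1 past the threshold (0.30 ± 0.07 SE). The call of Msmo1 ended without any 1 of 7 arrays (adjusted p up to 0.116). The same held for intestinal stem cell genes (0.11 ± 0.07 SE, camera adjusted p = 0.0251, and adjusted p = 0.636 with an estimated correlation), where Lgr5 was at 0.38 ± 0.13 (SE, adjusted p = 0.183 in limma), and for proliferation genes (0.13 ± 0.10 SE, camera adjusted p = 0.000121, and adjusted p = 0.636 with an estimated correlation), of which none of 39 passed. Smooth muscle genes (−0.14 ± 0.13 SE, camera adjusted p = 0.0027) and endothelial genes (−0.10 ± 0.09 SE, camera adjusted p = 0.0482) were lower by camera alone, with adjusted p = 0.636 and 0.645 with an estimated correlation.

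Paneth cell genes were not called (0.22 ± 0.17 SE, adjusted p = 0.385 by exact permutation), although 3 of 13 rose: Reg4, Mptx1 and Spink4 (0.86 ± 0.16 SE; adjusted p = 0.0517 without TUDCA replicate 2), with lysozyme Lyz1 at −0.12 ± 0.27 (SE, adjusted p = 0.898). RegIII and epithelial defence genes were not called (0.02 ± 0.08 SE), with Sprr1a and Reg1 (0.85 ± 0.13 SE) higher and Reg3g at −0.45 ± 0.16 (SE, adjusted p = 0.197). Circadian clock genes were not called as a list (−0.02), although 3 of 16 fell, namely Cry2 (−0.57 ± 0.09 SE), Npas2 (−0.43 ± 0.09 SE) and Nfil3 (−0.49 ± 0.10 SE), and 2 rose, 1 of them Bhlhe40 (0.54 ± 0.11 SE).

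Neither test called the other lists. Score differences were 0.05 for tight junction genes, 0.03 for enteroendocrine and tuft cell genes, −0.02 for extracellular matrix genes and 0.02 for enteric neuron and glia genes. They were −0.03 for CXCL12-abundant reticular cell markers, −0.13 for pancreas, fat and mesothelium genes and 0.20 for erythroid genes (adjusted p = 0.0622 by exact permutation). Only 7 of 16 erythroid genes were measured, with a median member difference of 0.04, and Car1 was the only 1 past the threshold. Of PPAR alpha and fatty acid oxidation genes (−0.09), Acot1 rose (0.49 ± 0.10 SE) and Vnn1 and the coactivator gene Ppargc1a (−0.39 ± 0.08 SE) fell. Of immediate early genes (0.03), Jun (−0.50 ± 0.11 SE) and Zfp36 (−0.39 ± 0.10 SE) fell and Hspa1a rose (0.44 ± 0.11 SE). Without the number range term the calls of Acot1, Ppargc1a, Jun, Zfp36 and Hspa1a ended (adjusted p = 0.0545, 0.172, 0.487, 0.218 and 0.301). Over the 12 arrays left out 1 at a time, the call of Hspa1a ended in 10 fits, that of Zfp36 in 9, Jun in 4, Acot1 and Nfil3 in 3, Npas2 and Bhlhe40 in 2 and Ppargc1a in 1. All of these ended without TUDCA replicate 1, with adjusted p over the left-out arrays up to 0.166 for Zfp36.

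The comparison of the number ranges, with treatment in the model, asks how far arrays differed apart from treatment. No probe set passed in limma (smallest adjusted p = 0.0781, 2523 at an unadjusted p under 0.05), while 18 passed with array weights and 2 with dim probe sets left out. By camera the interferon gamma response genes were higher in the high range (score difference 0.43, adjusted p = 2.8e-17, adjusted p = 0.284 with an estimated correlation), as were T and NK cell markers (0.22, adjusted p = 3e-06, adjusted p = 0.497 with an estimated correlation), and smooth muscle genes were lower (−0.18, adjusted p = 6.28e-05, adjusted p = 0.506 with an estimated correlation). By camera, type I interferon (0.31), inflammatory (0.17), MHC class I (0.13) and immediate early genes (0.12) were also higher in the high range. Bile acid (−0.19), goblet cell (−0.15), glutathione (−0.13), stem cell (−0.12), proliferation (−0.11) and cholesterol synthesis genes (−0.09) were lower, and none of these lists passed with an estimated correlation (adjusted p from 0.284 to 0.59 with an estimated correlation). Since the high range held more TUDCA arrays, the interferon gamma difference between treatments was estimated within each range, at −0.86 in the low and −0.32 in the high range. In the low and the high range the differences were −0.47 and −0.25 for MHC class I, −0.36 and −0.17 for class II and −0.58 and −0.23 for T and NK cell markers. They were −0.41 and −0.18 for enterocyte, −0.29 and −0.23 for bile acid, 0.32 and 0.23 for goblet cell and 0.25 and 0.09 for glutathione genes. In each of these 8 lists all 6 TUDCA arrays lay in the direction of the difference from the vehicle mean of their range. The lists were called on these same arrays, so this is no separate support. The treatment differences in the ranges were not shown to differ for any probe set (0 past the threshold for the interaction in limma, smallest adjusted p = 0.101, 1843 at an unadjusted p under 0.05).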

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

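A search for arrays far from the rest of their group, over 105 named genes and 35 list scores in each group, returned 17 cases in 280 tests, where chance at 1 in 20 gives about 14. TUDCA replicate 2 had the lowest log2 value for S100g (7.34, the next at 9.21), Tap1 (9.24, the next at 9.76), Cd8b1 (6.65, the next at 7.27), Cd3e (6.69, the next at 7.54) and Il1b (4.79, the next at 5.71), and the lowest pro-apoptotic score (−0.093, the next at −0.015). TUDCA replicate 1 had the highest Nrg1 value (8.54, the next at 7.74), and TUDCA replicate 6 the highest Epha2 value (9.26, the next at 8.60) and the highest type I interferon score (0.68, the next at −0.05). TUDCA replicate 4 had the lowest Ddit3 value (6.79, the next at 7.17), and TUDCA replicate 3 the highest PPAR alpha and fatty acid oxidation score (0.17, the next at −0.05). Among vehicle arrays, replicate 5 had the lowest Ubd value (8.35, the next at 9.08), the highest ER stress score (0.14, the next at −0.02) and the lowest smooth muscle score (−0.42, the next at 0.09). Vehicle replicate 4 had the highest Bhlhe40 value (9.48, the next at 9.06) and the lowest enteroendocrine and tuft cell score (−0.16, the next at −0.01), and vehicle replicate 6 had the highest Jun value (10.02, the next at 9.43).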

How the results depend on the processing

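All alternatives were planned before the data were examined. Of the 89 named genes past the threshold, 47 stayed past it whichever array was left out. The calls of 39 ended without TUDCA replicate 1, of 33 without TUDCA replicate 2, of 20 without the number range term, of 21 in the low range alone and of 85 in the high range alone. Left-out arrays gave 91 to 292 probe sets higher, 151 to 417 lower and 0 to 11 between number ranges, inflammatory score differences of −0.24 to −0.11 and ER stress differences of 0.0080 to 0.095. The high range alone gave 6 probe sets higher and 3 lower, 2 lists higher, an inflammatory difference of −0.10 and an ER stress difference of −0.058, called by camera against the sign over all arrays. Values that passed in neither fit also changed sign under some settings. The low range alone gave 8 lists higher and an ER stress difference of 0.13. The inflammatory difference lost its camera call without the number range term (−0.12) and with array weights (−0.13). Array weights gave 436 probe sets higher and 18 between number ranges, and a threshold of 0.1 gave 429 higher. Leaving out dim probe sets gave 2 between number ranges and an inflammatory difference of −0.33, still called by camera. With an estimated correlation 0 lists were higher and 0 lower, which ended the calls of the lists for MHC class I (−0.36), class II (−0.27), interferon gamma (−0.59), bile acids (−0.26) and inflammatory genes (−0.17). The estimated correlations of the 8 lists called by both tests ran from 0.033 (glutathione) to 0.52 (interferon gamma), all above the preset of 0.01. The p-values by camera at the preset can therefore overstate these calls. With fry 1 list was higher and 4 lower, and the bile acid (−0.26), inflammatory (−0.17), goblet cell (adjusted p = 0.056) and T and NK cell (adjusted p = 0.0826) calls ended. The cause of the other changes was not tested.

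The replicate number as a block together with the number range gave 85 probe sets higher and 190 lower and ended the calls of 31 of the 89 named genes, and as a block without the range an inflammatory score difference of −0.12 that lost its call. Deviations from the group means were correlated between the TUDCA and the vehicle array of each of the 6 replicate numbers. These correlations lay between −0.06 and 0.26, with 3 of 6 over 0.1. Since the labels name nothing that a number shares and not every pair passed 0.1, the numbers were not treated as pairs. In 4 of 6 the own number was the best partner, a hint from the data of shared variation. The number range was left in the deviations, so where both arrays of a number share a range its part cannot be told apart. The cause was not tested.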

Other observations

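Apart from the chance regroupings of arrays, the test of class I genes with T and NK cell markers as a covariate and the epithelial share test of the ERK feedback and hypoxia genes, the tests in this part were chosen only after the results were seen. So were the gene groups that follow, written after called genes had been read, and the hypoxia group after all of them. The directions and p-values of all these groups can be partly given by that choice and are no independent evidence. The adjustment ran over the added groups alone, so their adjusted p is not comparable with that of the lists fixed beforehand. Genes of intraepithelial lymphocytes and the butyrophilin-like proteins that maintain them fell in the treated intestine. Of 9 measured genes, 3 of them shared with the T and NK cell list, 6 fell (8 when adjusted over the list alone), among them Cd7 (−1.22 ± 0.24 SE), Btnl1 (−0.39 ± 0.07 SE) and Btnl2 (−0.39 ± 0.06 SE), with a score difference of −0.77 ± 0.14 (SE, adjusted p = 0.0107 by exact permutation, adjusted p = 0.00986 with an estimated correlation). The calls of Cd7 and Btnl1 ended without TUDCA replicate 1 (adjusted p = 0.0622 and 0.0597), and that of Cd7 also without TUDCA replicate 2. Pan-leukocyte genes were lower too (−0.39 ± 0.13 SE, adjusted p = 0.0178 by exact permutation, adjusted p = 0.101 with an estimated correlation). TUDCA replicate 2 had by far the lowest pan-leukocyte score (−0.66, the other TUDCA arrays from −0.25 to 0.071). Vitamin D response genes were lower by −0.23 ± 0.04 (SE, adjusted p = 0.0107 by exact permutation, adjusted p = 0.0347 with an estimated correlation), with Trpm6, a magnesium channel, the 1 of 9 past the threshold (−0.84 ± 0.19 SE). The call of Trpm6 ended without any 1 of 6 arrays (adjusted p up to 0.155).

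Genes of hypoxia and glycolysis rose: 10 of 32 were higher and none lower (18 and 2 when adjusted over the list alone), including the glucose transporter Slc2a1 (0.87 ± 0.13 SE), the oxygen sensor Egln3 (0.78 ± 0.16 SE) and the glycolytic enzyme Pgk1 (0.42 ± 0.08 SE). The score difference was 0.24 ± 0.03 (SE, adjusted p = 0.0107 by exact permutation, adjusted p = 0.00491 with an estimated correlation). Genes of ERK and EGF receptor feedback rose (0.25 ± 0.03 SE, 3 of 18 genes, adjusted p = 0.0107 by exact permutation, adjusted p = 0.0049 with an estimated correlation), with Epha2 (0.79 ± 0.18 SE), Plaur, the urokinase receptor (0.63 ± 0.12 SE), and Spry2 (0.29 ± 0.07 SE). Genes of fetal-like, regenerating epithelium rose (0.33 ± 0.04 SE, 5 of 17 genes, adjusted p = 0.0107 by exact permutation, adjusted p = 0.00919 with an estimated correlation), with Anxa2 (0.40 ± 0.06 SE), Emp1 (0.91 ± 0.13 SE) and S100a6 (0.76 ± 0.16 SE). Over the 12 arrays left out 1 at a time, the call of Spry2 ended in 10 fits, that of Epha2 in 4 (TUDCA replicates 1 and 2, vehicle replicates 5 and 6), Plaur in 2 (TUDCA replicates 1 and 2) and S100a6 in 2 (TUDCA replicate 2, vehicle replicate 5), with adjusted p up to 0.14, 0.1, 0.0589 and 0.105. Without the number range term the call of Spry2 ended too (adjusted p = 0.0875), and without TUDCA replicate 1 those of Egln3 and Pgk1 (adjusted p = 0.0845 and 0.0681).

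Other added groups did not pass by exact permutation. By camera alone villus tip genes were lower (−0.16, adjusted p = 0.0412, adjusted p = 0.373 with an estimated correlation) and pan-epithelial genes higher (0.10, adjusted p = 0.0167, adjusted p = 0.373 with an estimated correlation, adjusted p = 0.061 by exact permutation). Neither test called villus bottom (−0.10), glucocorticoid response (0.04) or xenobiotic metabolism genes (−0.03). Higher YAP activity, a driver of intestinal regeneration, was tested as a hypothesis for the regenerating genes, and the YAP target difference was −0.05 with an upper 95% limit of 0.095. Its 21 members went both ways (SD of 0.25 around a median of −0.02), so higher YAP activity in part of its targets stays open.

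Of 100 regroupings of the 12 arrays into 6 and 6, the real grouping included, 1 called as many as 605 probe sets, the highest other calling 29, and 2 called as many as 17 lists by camera, the highest other calling 17. Regrouped within the number ranges, as in the model, 1 of 100 called as many probe sets and 4 called as many lists, with the highest others at 244 probe sets and 19 lists. Both counts argue against chance for the probe sets, while the lists were matched or exceeded by some regroupings in each case. For the number ranges 100 of 100 regroupings called at least the real 0 in limma (2523 at an unadjusted p under 0.05; highest other 4), which any count of 0 must give, so this decides nothing about the ranges.

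For the lower interferon gamma and antigen presentation genes, a leak from the number ranges would not give differences within each range. The mean score difference of the 3 lists was −0.56 in the low and −0.25 in the high range. Its exact permutation p of 0.00444, the smallest it can give, adds no support, since the same test within ranges had called each of the 3 lists. T and NK markers fell relative to neutrophil and mast cell markers (−0.50, exact permutation p = 0.00889), which argues against an equal fall of these markers only. Pan-leukocyte genes were at −0.39 with all 15 measured members below 0, beside −0.41 for T and NK markers. A wider loss of white blood cells thus stays open. With T and NK cell markers as a covariate, a class I difference of −0.24 ± 0.07 (SE) remained. Those of class II (−0.13 ± 0.07 SE) and interferon gamma genes (−0.22 ± 0.14 SE) were not clearly apart from 0. A marker score tracks cell numbers with error, so the remaining class I difference cannot exclude fewer T and NK cells. For all 3 lists this stays open. A loss of class II transcripts of donor cells could not account for class II in full, since H2-Ea, which C57BL/6 cells do not express, was at −0.69 (adjusted p = 0.0137 in limma), while an effect of fewer donor T cells on recipient cells stays open.

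For the lower enterocyte and higher goblet cell genes, a lower epithelial share is argued against by pan-epithelial genes at 0.10, with a lower 95% limit of 0.0085. The pan-epithelial difference was 0.19 in the low and only 0.0092 in the high range. A trend with brightness is argued against by the enterocyte median lying at percentile 0 of 10000 brightness-matched random lists. Sampling of another segment cannot be told apart, since the jejunal minus ileal contrast of 0.14 had a 95% interval from −0.11 to 0.38 (exact permutation p = 0.231).

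For the higher ERK feedback and hypoxia genes, tissue handling before lysis cannot be told apart: immediate early genes were at 0.03 with an upper 95% limit of 0.14, but members went both ways (SD of 0.27 around a median of −0.0055). A larger epithelial share was examined in a test written before its result was seen, on groups chosen after called genes had been read. With the pan-epithelial score as a covariate, a mean difference of 0.24 ± 0.02 (SE) remained, so this score did not account for it. A marker score tracks the epithelial share with error, so a larger share stays open. Whether only the members already seen as called moved cannot be told apart from a rise of the whole lists. The 37 other members had a mean difference of 0.15, but they were set apart by the threshold on the same arrays, in lists written with called genes known. A response of the epithelium to TUDCA stays a hypothesis, found and tested on the same arrays.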
